A study of Mus musculus with 17 samples.

How the data were processed

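The series held single-cell RNA sequencing of CD45+ cells, the surface marker of white blood cells and microglia, sorted by flow cytometry from the cortex of 6-month-old female mice. Per the labels, 12 libraries came from mice with floxed Syk alleles: Syk_fl, creER_Syk_fl, Syk_fl_5XFAD and creER_Syk_fl_5XFAD, with 3 libraries each. A second cohort of 5 libraries came from 5XFAD mice with intact Trem2 (Trem2_WT_5XFAD, 2 libraries) or without it (Trem2_KO_5XFAD, 3 libraries). The 5XFAD transgenes give an amyloid plaque model of Alzheimer's disease. The creER carriers differed from Syk_fl in the Cx3cr1-creER allele as well as in the Syk deletion meant to follow from it, so these were compared as 1 difference. Groups came from the labels alone. The labels gave replicate numbers and did not say that they mark litters, days or batches.

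The deposited matrices held counts of unique molecular identifiers (UMIs) per gene and cell barcode for 21835 genes. The deposited barcode and gene tables had the unit other, since they held cell barcodes, gene identifiers and symbols. The labels listed Cell Ranger 6.0.0, Seurat 4.0 and R 4.1.0 with the genome build GRCm39 (mm39). No annotation of that build was used here, so no coordinates are given.

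Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes. Doublets were scored per library against 2 simulated doublets per cell over 1000 variable genes and 20 principal components. The planned threshold between the peaks of the score called almost no cells, so the highest scores were removed at an expected rate of 0.8% per 1000 barcodes, a choice made after the scores were seen. Counts were log-normalised, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (python-igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) gave the clusters. A cluster was named from fixed markers of 19 cell classes among its 10 leading genes, with at least 3 markers detected in 10% of its cells. Where none of the 10 was a marker, the class with the most markers at a fold over 2, at least 3, gave the name. Cluster 9 had low UMIs and no marker among its 10 leading genes and was left unnamed. Microglia made up most cells, so their clusters did not stand out against all others; these were named in a second step against the cells of the other named classes, a step added after the first one was run. Clusters without a name were left out of the gene comparisons.

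UMI counts of the cells called microglia-like were summed per library, which made the library the unit of replication. All 17 sums entered 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with a mean per group, TMM scaling and the filterByExpr filter, which left 12352 genes and 11 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, the counts scaled to each library's normalised total, with the SD between libraries.

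The contrasts were 5XFAD with Syk intact, 5XFAD in creER Syk fl/fl, creER within 5XFAD, creER without 5XFAD, the interaction of 5XFAD with creER, Trem2 knockout within 5XFAD, the difference between the creER and Trem2 knockout changes, and the difference between the cohorts. The interaction tests whether the 5XFAD change differs between creER Syk fl/fl and Syk fl/fl. The lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. There were 20 gene lists: homeostatic, DAM (disease-associated microglia) stage 1, DAM stage 2, interferon response, MHC class II, MHC class I, cholesterol synthesis, lipid export and storage, lysosome, glycolysis, oxidative phosphorylation, ATF4 and amino acid, NF-kB cytokines, immediate early and dissociation, cell cycle, ITAM signalling, complement, autophagy, ribosomal protein and other lineage. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, then with an estimated correlation and with fry. Some genes belong to more than 1 list, and Trac, Ighm and Mx1 were among the listed genes absent from the gene tables.

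Named genes were Syk, Trem2 and Cx3cr1, then up to 6 with the largest rise and 6 with the largest fall among called genes with a mean of at least 20 CPM and no overlap between the libraries of the groups. To these came up to 2 called members of each list that passed. Some genes the rule names are not reported here, though they stay in every fit and count. Absence of overlap arises by chance in 10% of comparisons of 3 with 3 libraries, and more often in the Trem2 comparison of 2 with 3. A group with 0 UMIs of a gene was given a floor of 3 counts over the group's pooled UMIs, and ratios against 1 to 3 UMIs have exact binomial 95% intervals. Intervals and floors cover counting error only.

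The share of microglia-like cells with high DAM UMIs was measured after thinning every cell to 2000 UMIs, as cells at or above the 95th percentile of the DAM stage 2 sum in Syk_fl cells. Shares were compared by two-sided exact permutation tests within strata. In the Syk cohort each difference was the mean over strata, Syk genotypes for 5XFAD and 5XFAD status for creER. The alternatives were DESeq2 size factors, no filter beyond 10 counts, the DESeq2 1.42.0 Wald test, fits to fewer libraries, a replicate block, thinned cells, kept doublets, a stricter cell filter (1000 genes, 5% mitochondrial), a minimum log2 fold change of 0.5, and each replicate left out. Some were added after seeing the data: keeping unnamed clusters with microglia markers, leaving out the 2 libraries that stood apart, thinned cells for the lists, no thinning for the DAM share, and the block for the correlation and the part kept. The 2 libraries were creER_Syk_fl_5XFAD replicate 3 and Trem2_WT_5XFAD replicate 1, and that they stood apart was not tested. The fit was tested on counts simulated from overall gene means and its own dispersions. Of genes given a 2-fold difference, 73.8% to 89.4% were called, depending on the contrast, with 3 to 11 false calls. These simulated counts held no other structure between libraries or cohorts.

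The matrices held 123625 barcodes and 12771595 to 72387162 UMIs per library. Of these barcodes, 117811 passed the filters, 7943 were removed as doublets, and 101286 of the remaining 109868 cells were microglia-like, at 10494955 to 59664918 UMIs per library. The common biological coefficient of variation between libraries was 0.111.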

Results

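The data describe CD45+ cells from the cortex of 17 mice, counted with the 10x 3′ v3 assay. Of the 109868 cells kept, 101286 were microglia-like, between 2566 and 10056 per library, and these cells carry the comparisons. The other named cells were border macrophage-like, monocyte-like, neutrophil-like, T cell-like and B cell-like. The groups were Syk_fl, creER_Syk_fl, Syk_fl_5XFAD, creER_Syk_fl_5XFAD and Trem2_KO_5XFAD with 3 libraries each, and Trem2_WT_5XFAD with 2. Libraries held 12771595 to 72387162 UMIs. The first principal component of the microglia-like sums took 61.2% of the variance and parted the Syk cohort from the Trem2 cohort, and the second took 13.6%.

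The targeted genes were read first. SYK is a kinase that signals below ITAM-coupled receptors, and TREM2 is a lipid-sensing microglial receptor that uses such an adaptor. Trem2 transcripts (ENSMUSG00000023992) fell to 189 to 216 CPM in the Trem2_KO_5XFAD libraries, against 3935 and 4747 CPM in the Trem2_WT_5XFAD libraries, a log2 fold change of -4.40 (SE 0.13, adjusted p = 2.08e-12). Cx3cr1 (ENSMUSG00000052336), the fractalkine receptor gene that holds the creER allele, fell in carriers from 7740 ± 827 to 3925 ± 38.6 CPM without 5XFAD (SD, n = 3 each; adjusted p = 0.000526, edgeR). Within 5XFAD it fell from 6662 ± 461 to 3557 ± 134 CPM (adjusted p = 0.000186, edgeR). Syk transcripts (ENSMUSG00000021457) were not lower in carriers: the creER libraries held 111 to 138 CPM and the Syk_fl and Syk_fl_5XFAD libraries 96.5 to 128 CPM (adjusted p = 0.841 without 5XFAD and 0.137 within it). The assay counts 3′ ends and does not read whether a floxed exon was removed.

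The first comparison asked how 5XFAD changed microglia-like cells with Syk intact. Transcripts of disease-associated microglia rose: Cst7, which encodes the protease inhibitor cystatin F, went from 12.1 ± 6.76 CPM in Syk_fl to 515 ± 174 CPM in Syk_fl_5XFAD (SD, n = 3 each), a 44.7-fold rise. Lipoprotein lipase (Lpl) rose 11.2-fold to 203 ± 49.6 CPM, the beta-glucan receptor Clec7a 11.2-fold to 196 ± 67.0 CPM, and Apoe, the main lipid carrier of the brain, 7.61-fold to 3363 ± 2025 CPM. In all, 507 genes rose and 57 fell among 12352. Trem2 itself rose from 2144 ± 145 to 2980 ± 434 CPM (adjusted p = 0.0151, edgeR), while Cx3cr1 stood at a log2 fold change of -0.22 (adjusted p = 0.276) and Syk at -0.22 (adjusted p = 0.243).

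By list, 17 of the 18 DAM stage 2 genes rose (18 adjusted over the list alone), at a mean log2 fold change of 2.35 and an adjusted p of 4.10e-23 with camera and 0.0685 with an estimated correlation. Gpnmb, a lysosomal membrane glycoprotein, had 3 UMIs in the Syk_fl group and 412 in Syk_fl_5XFAD, a pooled ratio of 134 (95% interval 45.6 to 653). DAM stage 1 had 8 of 10 genes up (10 adjusted over the list alone), among them Apoe and lysozyme (Lyz2, log2 fold change 1.52, SE 0.25); its adjusted p = 0.0685 with an estimated correlation. Interferon response genes rose in 17 of 19 cases (18 adjusted over the list alone; adjusted p = 0.0685 with an estimated correlation), led by Ifi27l2a at 3.45 (SE 0.47) and Oasl2 at 2.83 (SE 0.41). Of 9 MHC class II genes, which present antigen to helper T cells, 7 rose (7 adjusted over the list alone): H2-Aa at 5.10 (SE 0.69), H2-Eb1 at 4.24 (SE 0.60) and the invariant chain Cd74 at 3.06 (SE 0.43). This list kept its call with an estimated correlation (adjusted p = 0.0406), as did cholesterol synthesis (adjusted p = 0.0406), where 9 of 19 genes rose (11 adjusted over the list alone). MHC class I rose in 6 of 9 genes (7 adjusted over the list alone), with its transcriptional activator Nlrc5 at 1.39 and H2-D1 at 1.07 (adjusted p = 0.0685 with an estimated correlation).

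**Figure D1:**
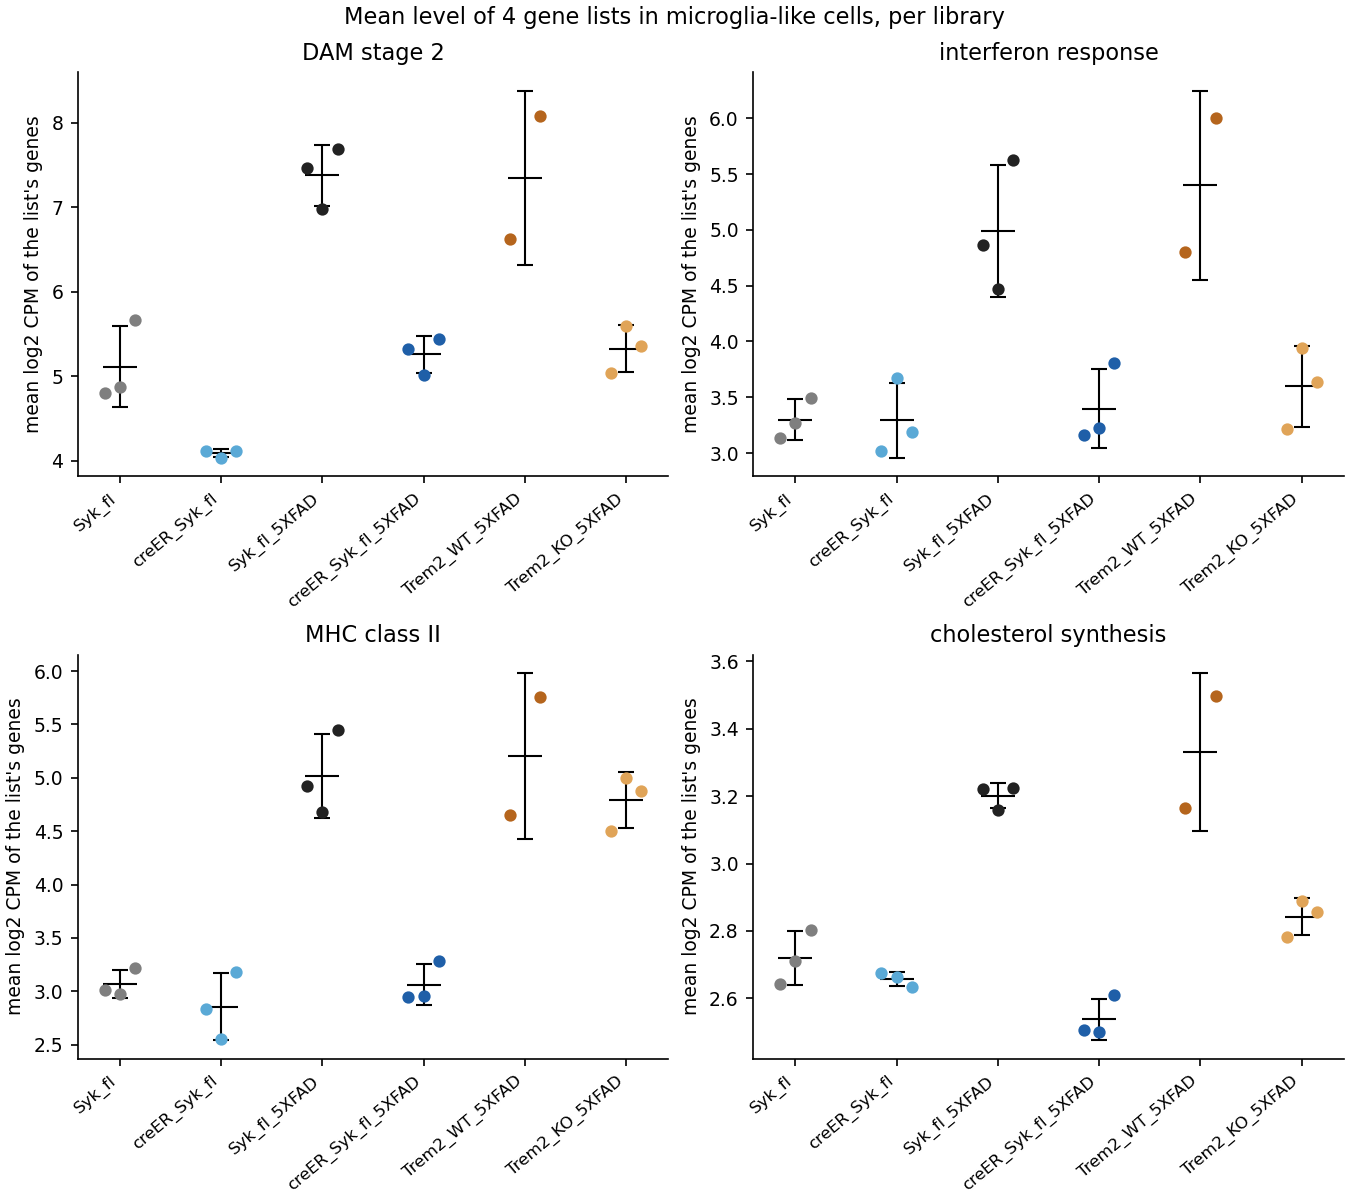
Each point is 1 library, and the vertical axis gives the mean log2 CPM of a list's genes in microglia-like cells; horizontal marks and bars are the group mean and SD (n = 3, or n = 2 for Trem2_WT_5XFAD). The DAM stage 2, interferon response, MHC class II and cholesterol synthesis lists stood higher in the 3 Syk_fl_5XFAD libraries than in the 9 other libraries of the Syk cohort.

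Lipid handling, lysosome and metabolic genes followed with smaller shares. In the lipid export and storage list 4 of 14 genes rose (6 up and 1 down adjusted over the list alone), among them cholesterol 25-hydroxylase (Ch25h) at a log2 fold change of 6.13 and the fatty acid binding protein Fabp5 at 4.63; adjusted p = 0.292 with an estimated correlation. Of 20 lysosome genes, 8 rose (11 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), with Cd63 at 0.68. Atp6v0d2, a proton pump subunit, had 0 UMIs in Syk_fl and 101 in Syk_fl_5XFAD, at least 32.9-fold higher over the pooled group. All 20 ribosomal protein genes rose, with Rpl32 at 0.75 and Rps19 at 0.72 (adjusted p = 0.0685 with an estimated correlation). Oxidative phosphorylation had 4 of 18 genes up (11 adjusted over the list alone), such as Ndufa1 at 0.86 and Uqcrh at 0.59, and glycolysis 3 of 14 (6 adjusted over the list alone), such as Gpi1 at 0.39 and Pgk1 at 0.37; these had adjusted p = 0.238 and 0.218 with an estimated correlation. The cell cycle list was called higher with 1 of 17 genes up (2 adjusted over the list alone), the mitotic kinase Cdk1 at 1.19 (adjusted p = 0.292 with an estimated correlation). The homeostatic list was called lower, with 1 of 20 genes down (4 adjusted over the list alone), the crystallin Crybb1 at -0.62 (adjusted p = 0.154 with an estimated correlation). Immediate early and dissociation genes were called lower as a list at a mean of -0.61 with none of 14 called (3 down adjusted over the list alone; adjusted p = 0.317 with an estimated correlation).

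Among called genes with a mean of at least 20 CPM and no overlap between libraries, the largest falls in 5XFAD with Syk intact were Sema4b at a log2 fold change of -0.72, the G protein regulator Rgs1 at -0.71, Crybb1 at -0.62, Nfkbia, the inhibitor of NF-kB, at -0.57, Tmem44 at -0.57 and the kinase Sgk1 at -0.55. No call was made for NF-kB cytokines (adjusted p = 0.539), complement (0.15), ATF4 and amino acid (0.143), ITAM signalling (0.798), autophagy (0.685) or other lineage (0.564). The mean and the median of the NF-kB cytokines and other lineage lists differed in sign, and ITAM signalling had a mean of 0.05 against a median of -0.04. The median of the autophagy list changed sign under DESeq2 size factors. The count of 564 genes moved with single libraries: it was 172 without Syk_fl_5XFAD replicate 3 and 197 without Syk_fl replicate 2.

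The second comparison asked what remained of the 5XFAD change in creER Syk fl/fl. Apoe rose 12.1-fold, from 128 ± 28.1 to 1545 ± 286 CPM (SD, n = 3 each), Clec7a 10.7-fold to 19.4 ± 7.15 CPM and Cst7 9.14-fold to 33.8 ± 8.28 CPM, so Clec7a and Cst7 ended far below their levels in Syk_fl_5XFAD. The chemokines Ccl4 and Ccl3 rose 5.38-fold to 80.6 ± 55.4 CPM and 4.90-fold to 80.8 ± 48.1 CPM, and Lyz2 rose 2.77-fold. The creER_Syk_fl_5XFAD libraries differed here: replicate 3 had a mean log2 CPM of 4.95 for NF-kB cytokines and 6.69 for immediate early genes, against 4.17 and 5.64 in replicate 1 and 4.04 and 5.93 in replicate 2. Interferon response and MHC class II genes stayed near their level without 5XFAD. In all, 69 genes rose and 8 fell, the latter led by Tmem176a at a log2 fold change of -0.58, cyclin D1 (Ccnd1) at -0.55, Tmem176b at -0.49 and Cass4 at -0.42. Trem2 stood at 0.44 (SE 0.11, adjusted p = 0.0814).

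Of the DAM stage 2 genes, 6 of 18 rose (13 adjusted over the list alone), at a mean log2 fold change of 1.30 (adjusted p = 0.159 with an estimated correlation). DAM stage 1 had 3 of 10 genes up (6 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). In the lysosome list Cd63 (1.15, SE 0.17), Cd68 (0.39, SE 0.09) and 1 more of 20 genes rose (11 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). The lipid export list was called with 1 of 14 genes up, Apoe (6 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). NF-kB cytokines had 3 of 14 up, Ccl4 and Ccl3 among them (3 adjusted over the list alone; adjusted p = 0.422 with an estimated correlation), and ribosomal protein none of 20 over all genes (19 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). The interferon response list had none of 19 genes called and a mean of 0.07 (adjusted p = 0.709), and MHC class II none of 9 and a mean of 0.13 (adjusted p = 0.343); for both, no member was called adjusted over the list alone. Cholesterol synthesis was called lower at a mean of -0.14 with none of 19 genes called (none adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). Smaller list calls, all lost with an estimated correlation, were homeostatic down (adjusted p = 0.36), and glycolysis (0.36), immediate early (0.46), cell cycle (0.615), autophagy (0.169) and other lineage (0.422) up, none of them with a member called over all genes, and apart from other lineage none adjusted over the list alone. The other lineage list, made of markers of blood and brain cells other than microglia, had 5 genes up and 1 down adjusted over the list alone, and its mean log2 CPM was 2.24 in creER_Syk_fl_5XFAD replicate 3 against 0.16 and -0.34 in replicates 1 and 2. The count of 77 genes was 50, 25 and 32 without creER_Syk_fl replicates 1, 2 and 3, 31 and 37 without creER_Syk_fl_5XFAD replicates 1 and 3, and 230 with the DESeq2 Wald test.

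The interaction asked whether the 5XFAD change itself differed by creER. Hacd2, a fatty acid elongation enzyme, stood at 56.0 ± 3.89 CPM in Syk_fl and 77.8 ± 6.26 CPM in Syk_fl_5XFAD, against 58.8 ± 3.01 and 52.0 ± 2.07 CPM in the creER groups without and with 5XFAD (SD, n = 3 each), an interaction of -0.65 on the log2 scale (SE 0.10, adjusted p = 0.0238, edgeR). The membrane protein gene Tmem176b stood at 386 ± 44.9 and 446 ± 14.2 CPM in Syk_fl without and with 5XFAD and at 438 ± 17.7 and 311 ± 7.76 CPM in carriers, an interaction of -0.70 (SE 0.11). Rapsn, known from the neuromuscular junction, went the other way at 0.82 (SE 0.12). The interaction called 6 genes in all (2 up, 4 down). Cholesterol synthesis was lower in the interaction at a mean of -0.66 (1 of 19 genes called, 11 adjusted over the list alone) and kept its call with an estimated correlation (adjusted p = 0.03). Interferon response stood at -1.71 (17 of 19 adjusted over the list alone, none over all genes; adjusted p = 0.178 with an estimated correlation), MHC class II at -1.93 (7 of 9 adjusted over the list alone, none over all genes; adjusted p = 0.061 with an estimated correlation) and DAM stage 2 at -1.05 (5 of 18 adjusted over the list alone, none over all genes; adjusted p = 0.541 with an estimated correlation). MHC class I, oxidative phosphorylation, cell cycle and ribosomal protein were called lower, and immediate early genes higher, with adjusted p = 0.309, 0.541, 0.625, 0.541 and 0.315 with an estimated correlation; of their genes, 10 of 14 immediate early genes were called adjusted over the list alone and none of the others. Mean and median differed in sign for the lipid export, lysosome, complement and ITAM signalling lists, none of which was called.

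As a ratio of mean log2 fold changes, creER carriers kept 83.8% of the DAM stage 1 rise, 61.5% of the ribosomal protein rise, 55.2% of DAM stage 2, 6.48% of MHC class II and 3.76% of interferon response; cholesterol synthesis stood at -28.0%. Each ratio starts from the carriers' own level without 5XFAD, which was lower for the DAM lists. Without 5XFAD the mean log2 fold change of carriers against Syk_fl was -1.15 for DAM stage 2 and -0.45 for DAM stage 1. Within 5XFAD, against Syk_fl_5XFAD, it was -2.20 and -0.60. The ratios thus do not give the part of the Syk_fl_5XFAD level that carriers reached. They also rest on means, and medians order the lists differently. With Syk intact and in carriers the median was 0.67 and 0.38 for DAM stage 1, 0.49 and 0.32 for ribosomal protein, 1.88 and 0.78 for DAM stage 2, 2.27 and 0.04 for MHC class II, 1.60 and 0.04 for interferon response and 0.27 and -0.04 for cholesterol synthesis. For lysosome the ratio was 40.9%, but its mean with Syk intact includes Atp6v0d2, with 0 UMIs in Syk_fl, and its medians were 0.19 and 0.19. The smallest ratios moved with single libraries: interferon response was -3.61%, 15.4% and 2.06% without creER_Syk_fl replicates 1, 2 and 3, and 10.2%, 8.87% and -8.92% without creER_Syk_fl_5XFAD replicates 1, 2 and 3. MHC class II was 4.04%, 1.51% and 17.3% without creER_Syk_fl replicates 1, 2 and 3, and 0.678% without creER_Syk_fl_5XFAD replicate 3. The interaction of DAM stage 1 was not called (adjusted p = 0.093). The 6 genes of the interaction were sensitive to single libraries: none was called with edgeR without creER_Syk_fl_5XFAD replicate 1, while with all libraries 1075 genes had an unadjusted p under 0.05 and DESeq2 called 123. The count was 3 without Syk_fl replicate 2, creER_Syk_fl replicate 2 or creER_Syk_fl_5XFAD replicate 2, 1 without creER_Syk_fl replicate 3 or Syk_fl_5XFAD replicate 3, and 28, 17 and 10 without Syk_fl replicate 3, Syk_fl_5XFAD replicate 2 and creER_Syk_fl_5XFAD replicate 3.

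**Figure D2:**
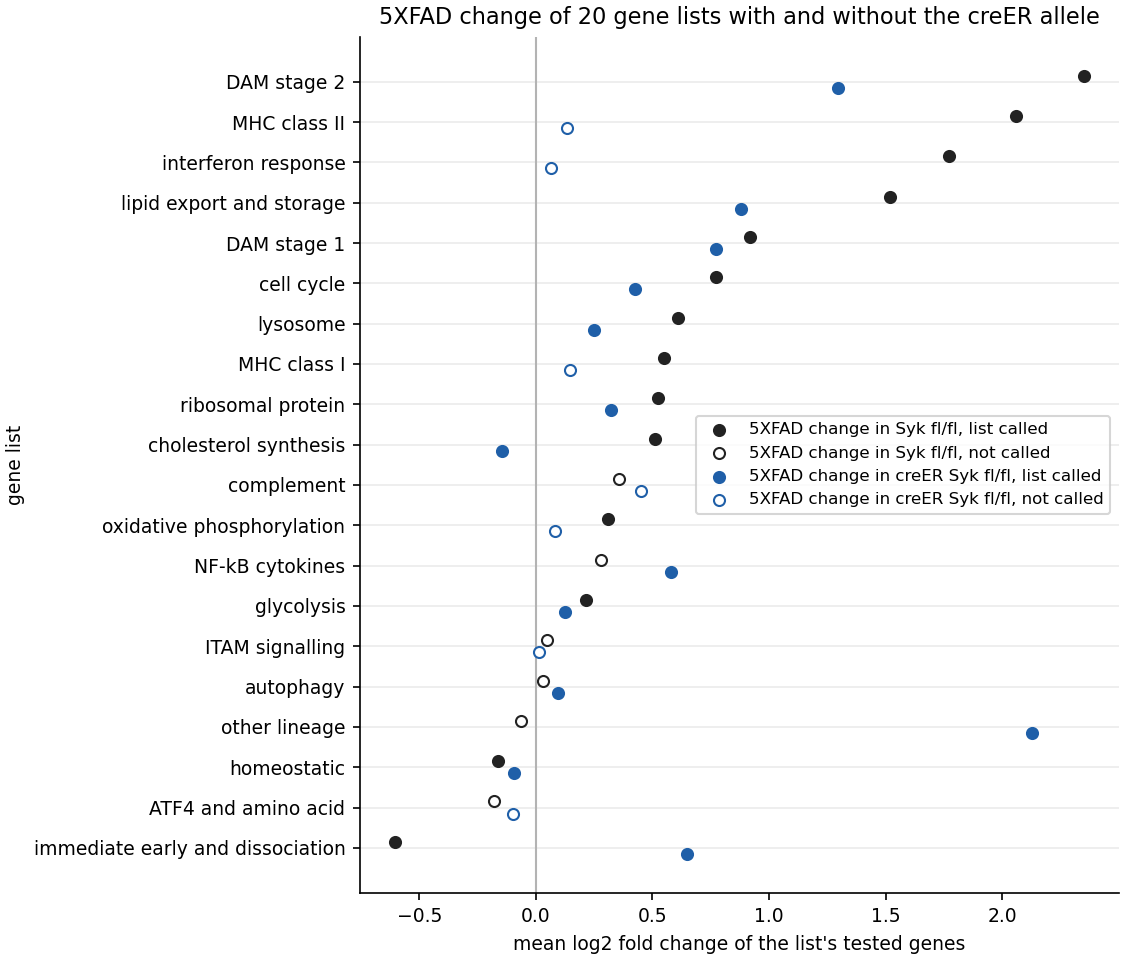
Points give the mean log2 fold change of each list's tested genes, black for 5XFAD in Syk fl/fl and blue for 5XFAD in creER Syk fl/fl; filled points were called by camera with the preset correlation and open points were not. The blue points of the interferon response and MHC class II lists sit at 0.07 and 0.13, against 1.77 and 2.06 for the black ones.

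The third comparison set creER_Syk_fl_5XFAD against Syk_fl_5XFAD. Lpl fell 22.1-fold, from 203 ± 49.6 to 9.37 ± 2.13 CPM (SD, n = 3 each), Cd74 16.5-fold to 10.1 ± 2.04 CPM, Cst7 15.3-fold to 33.8 ± 8.28 CPM and Clec7a 10.3-fold to 19.4 ± 7.15 CPM. The MHC class II gene H2-Ab1 fell 7.78-fold and the interferon-induced Ifi27l2a 5.65-fold. Altogether 320 genes fell and 44 rose. The rises were small in genes such as Tmem44, at a log2 fold change of 0.62, Chst8 at 0.52, Khdrbs3 at 0.50, transglutaminase 2 (Tgm2) at 0.46 and Rapsn at 0.46. Trem2 stood at -0.20 (SE 0.11, edgeR adjusted p = 0.475). The other lineage list was not called (camera adjusted p = 0.651), at a mean of 1.68 and a median of 0.11. Adjusted over the list alone, 4 of its genes were up and 1 down. As in the second comparison, creER_Syk_fl_5XFAD replicate 3 stood above its group's other libraries in this list.

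Of the DAM stage 2 genes 13 of 18 fell (16 adjusted over the list alone; adjusted p = 0.0593 with an estimated correlation), with Gpnmb at -5.93 (SE 1.08) and the receptor kinase Axl at -4.62 (SE 0.57). Interferon response genes fell in 15 of 19 cases (18 adjusted over the list alone; adjusted p = 0.0593 with an estimated correlation), with Ifi204 at -2.64 and Oasl2 at -2.50. MHC class II lost 5 of 9 (6 adjusted over the list alone), H2-Aa at -4.67 and H2-Eb1 at -4.23, and kept its call with an estimated correlation (adjusted p = 0.0446). Cholesterol synthesis fell in 10 of 19 genes (12 adjusted over the list alone) and kept its call as well (adjusted p = 0.00319). MHC class I fell in 4 of 9 genes (7 adjusted over the list alone; adjusted p = 0.0593 with an estimated correlation), with Nlrc5 at -1.21 and H2-D1 at -1.10. DAM stage 1 had 2 of 10 genes down (9 adjusted over the list alone), the MHC class I gene H2-D1 and its partner beta-2 microglobulin (B2m) at -0.77 (adjusted p = 0.107 with an estimated correlation).

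Glycolysis fell in 3 of 14 genes (7 adjusted over the list alone), Tpi1 at -0.46 and Pgk1 at -0.42 among them, and NF-kB cytokines in 3 of 14 (5 adjusted over the list alone), with interleukin 1 beta (Il1b) at -1.89 and the chemokine Cxcl16 at -0.84; these had adjusted p = 0.0593 and 0.213 with an estimated correlation. The lysosome list had 1 of 20 genes down (6 adjusted over the list alone), Atp6v0d2, with 0 UMIs in carriers and at least 44.4-fold lower over the pooled group (adjusted p = 0.232 with an estimated correlation). Oxidative phosphorylation (Ndufa1 at -0.68), ribosomal protein (Rps27 at -0.45) and complement were called lower with 1 of 18, 1 of 20 and none of 11 genes down (1, 5 and 3 adjusted over the list alone; adjusted p = 0.386, 0.232 and 0.255 with an estimated correlation). The homeostatic list was called higher with 1 gene up, the fructose transporter Slc2a5 at 0.36, and 1 down, Cx3cr1 (4 up and 1 down adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). The 364 genes were 158 without Syk_fl_5XFAD replicate 3, 150 without creER_Syk_fl_5XFAD replicate 1 and 197 without its replicate 2.

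The fourth comparison asked for the creER difference without 5XFAD. Chemokine transcripts were lower in carriers: Ccl4 fell 9.58-fold, from 143 ± 50.1 to 14.8 ± 4.29 CPM (SD, n = 3 each), and Ccl3 6.62-fold, from 109 ± 24.7 to 16.4 ± 2.91 CPM. Clec7a fell 9.83-fold to 1.75 ± 0.351 CPM, the integrin Itgax 5.36-fold, the urokinase receptor Plaur 2.30-fold and the activation marker Cd83 2.16-fold. The cells also lay in other clusters, which was not tested: cluster 0 (Gpr165, Khdrbs3) made up 19.0% ± 1.40 of microglia-like cells in Syk_fl and 38.0% ± 0.583 in carriers. Cluster 2 (Epb41l3, S1pr1) made up 20.4% ± 3.63 and 8.58% ± 0.397, and cluster 5 (Fosb, Egr1, Jun, Fos) 17.3% ± 10.8 and 3.40% ± 1.83. Only 6 genes rose against 38 that fell, with Khdrbs3 at a log2 fold change of 0.51 and Fat3, a cadherin, at 0.49. NF-kB cytokines fell in 5 of 14 genes (9 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation) and DAM stage 2 in 2 of 18 (10 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation). Immediate early genes, markers of stress in cell isolation, moved with them as a list, at a median of -0.93 with none of 14 called (8 adjusted over the list alone; adjusted p = 0.308 with an estimated correlation). DAM stage 1, lysosome and glycolysis were also called lower and cell cycle higher, with no gene called (4, 5, 8 and 0 adjusted over the list alone; adjusted p = 0.37, 0.225, 0.225 and 0.461 with an estimated correlation). Interferon response (mean 0.03, adjusted p = 0.555) and MHC class II (mean -0.12, adjusted p = 0.912) were not called. The 44 genes were 13 without Syk_fl replicate 2, 11, 10 and 21 without creER_Syk_fl replicates 1, 2 and 3, 89 without Syk_fl replicate 1, and 219 with DESeq2.

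The fifth comparison asked what Trem2 knockout did within 5XFAD. Cst7 fell 21.1-fold, from 850 ± 720 CPM in the 2 Trem2_WT_5XFAD libraries to 39.8 ± 15.8 CPM in the 3 knockout libraries (SD), Lpl 10.6-fold to 15.1 ± 6.07 CPM, Clec7a 8.70-fold to 10.9 ± 4.02 CPM and Apoe 5.01-fold to 807 ± 272 CPM. The interferon-induced genes Ifi27l2a and Ifitm3 fell 9.42-fold and 5.21-fold. In all, 138 genes fell and 16 rose, the latter by little: Rapsn at a log2 fold change of 0.44, Znhit3 at 0.42, Gabpb1 at 0.38, Pde12 at 0.37, Flot1 at 0.34 and Rab3ip at 0.30. DAM stage 2 had 10 of 18 genes down (17 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), with Axl at -4.45 (SE 0.63) and Gpnmb at -5.29 (SE 1.12). Interferon response had 13 of 19 down (19 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), with Oasl2 at -2.81 (SE 0.45). Cholesterol synthesis had 4 of 19 down (9 adjusted over the list alone), with Sqle, the squalene epoxidase, at -2.28 (SE 0.50), and kept its call with an estimated correlation (adjusted p = 0.0284). Lipid export had 4 of 14 down (7 down and 1 up adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), with Ch25h at -5.00 (SE 0.73) and Fabp5 at -4.27 (SE 0.75).

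In the knockout the MHC class II list was called lower at a mean of -0.59 with none of 9 genes called (2 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). DAM stage 1 and MHC class I each had 1 gene down over all genes (7 of 10 and 5 of 9 adjusted over the list alone; both adjusted p = 0.215 with an estimated correlation), Apoe in the former and Nlrc5 at -2.12 in the latter. Glycolysis had Pgk1 down at -0.43 (5 of 14 adjusted over the list alone), and lysosome, oxidative phosphorylation, cell cycle and ribosomal protein were called lower and homeostatic higher with no gene called (7 of 20 lysosome genes adjusted over the list alone, none of the others). In that order these 6 lists had adjusted p = 0.215, 0.264, 0.671, 0.336, 0.354 and 0.309 with an estimated correlation. The 154 genes rested on few libraries: the count was 7 without Trem2_WT_5XFAD replicate 2, 517 without its replicate 1, and 60, 86 and 83 without Trem2_KO_5XFAD replicates 1, 2 and 3. It was 313 with DESeq2 and 15 in a fit to the Trem2 cohort alone.

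The creER and Trem2 knockout changes within 5XFAD, which share no library, were then set side by side. They come from different cohorts, so the test of their difference can also hold a difference in batch or background. Of the 320 genes lower in creER carriers and 138 lower in the knockout, 108 were lower in both, against 3.58 for independent lists, 2 were higher in both, and none was called in opposite directions; Cst7, Lpl, Axl, Oasl2 and Ifi27l2a were among those lower in both. The 108 became 1 without Trem2_WT_5XFAD replicate 2 and 207 without its replicate 1, and 41, 63 and 50 without Trem2_KO_5XFAD replicates 1, 2 and 3. Without creER_Syk_fl_5XFAD replicate 1 it was 71. Of the 320, 314 had a negative change in the knockout, and of the 138, 132 had one in carriers. Over the 12352 genes tested, which are not independent replicates, Pearson's r was 0.536 and Spearman's rho 0.343. Without Trem2_WT_5XFAD replicate 2 these were 0.269 and 0.176. The test of the difference called 6 genes, among them Trem2 (4.19 on the log2 scale, SE 0.16) and Cx3cr1 (-0.96, SE 0.15), and 11 without Trem2_WT_5XFAD replicate 1. MHC class II was lower in carriers than in the knockout, each against its control, at a mean of -1.46 (none of 9 genes over all genes, 4 adjusted over the list alone), as was NF-kB cytokines at -0.57, while cell cycle stood at 1.05 and lipid export at 0.34; each call was lost with an estimated correlation (adjusted p = 0.984).

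**Figure D3:**
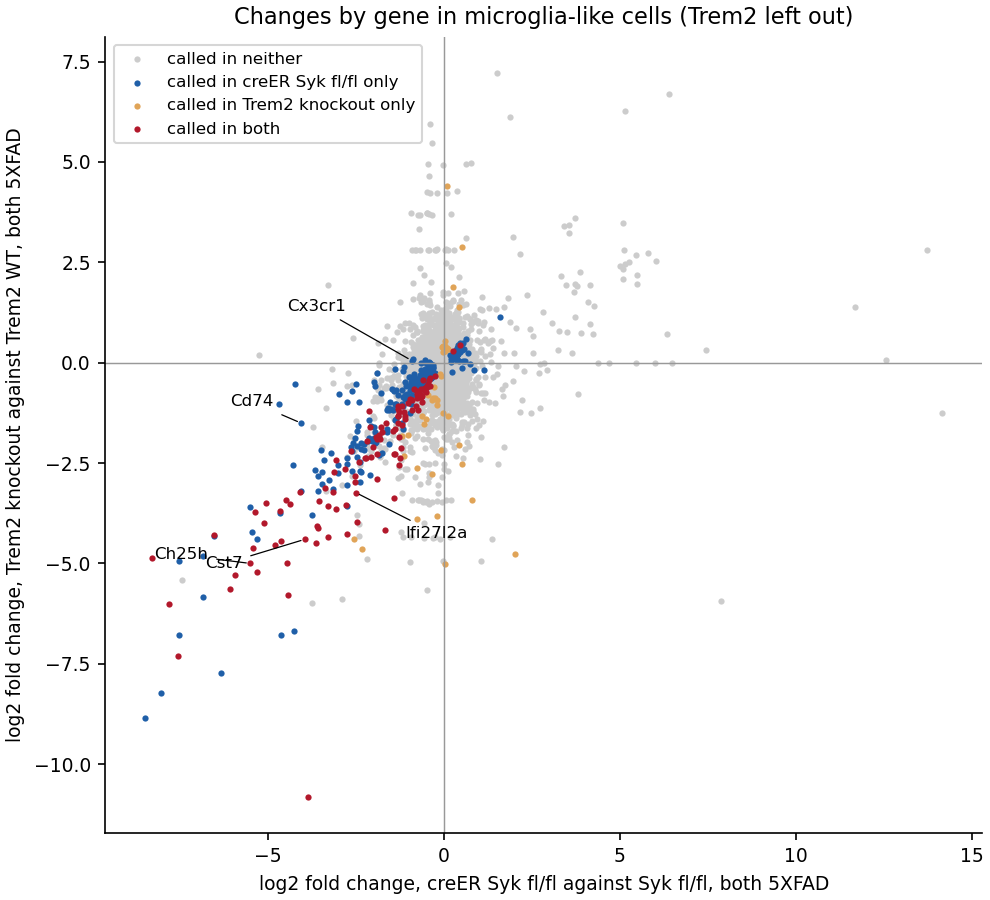
Each point is a gene tested in microglia-like cells, with the log2 fold change of creER Syk fl/fl within 5XFAD on the horizontal axis and that of Trem2 knockout within 5XFAD on the vertical axis; colours give the calls at an adjusted p under 0.05. The genes called lower in both, 108 with all libraries and 1 without Trem2_WT_5XFAD replicate 2, lie at the lower left, and Trem2 (-4.40 in the knockout) is left out.

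The DAM change was also read cell by cell. With every cell thinned to 2000 UMIs, 5.14% ± 2.48 of Syk_fl cells held high DAM stage 2 UMIs (SD, n = 3), against 22.6% ± 7.72 in Syk_fl_5XFAD, 0.923% ± 0.211 in creER_Syk_fl and 10.5% ± 1.92 in creER_Syk_fl_5XFAD (n = 3 each). Two-sided exact permutation tests gave a 5XFAD difference of 13.5 points, averaged over the Syk genotypes. The creER difference was -8.16 points, averaged over libraries with and without 5XFAD. Both had an exact p = 0.005, the smallest the design allows (adjusted p = 0.0075, 3 tests). The creER difference within 5XFAD was not tested alone. Trem2_WT_5XFAD libraries held 18.3% and 38.3%, and knockout libraries 13.2% ± 2.80 (n = 3), a difference of -15.1 points at an exact p = 0.1, again the smallest possible. The shares depend on the threshold. At the 99th percentile they were 1.01% ± 0.786 in Syk_fl, 13.5% ± 4.79 in Syk_fl_5XFAD, 0.0818% ± 0.0312 in creER_Syk_fl and 2.46% ± 0.654 in creER_Syk_fl_5XFAD, and 14.6% ± 9.93 against 3.12% ± 0.925 for intact and knocked out Trem2 (n = 2 and 3). At the 99th percentile the differences were 7.45, -5.99 and -11.5 points, at the same exact p. Without thinning, the shares at the 95th percentile were 19.2% ± 6.91 in Syk_fl_5XFAD, 8.67% ± 2.14 in creER_Syk_fl_5XFAD, 14.8% ± 11.5 with intact Trem2 and 3.28% ± 1.05 in the knockout, a Trem2 difference of -11.5 points. Of T cell-like cells, 3.39% (42 of 1238) reached the main count over all libraries. They held a mean of 8.55 UMIs of the list per thinned cell, against 8.12 in microglia-like cells of creER_Syk_fl, so they did not lack these transcripts. The T cell-like share was 4.55% (4 of 88) in Syk_fl and 3.33% (4 of 120) in creER_Syk_fl. With 5XFAD it was 1.61% (6 of 372) in Syk_fl_5XFAD, 2.48% (5 of 202) in creER_Syk_fl_5XFAD, 4.62% (8 of 173) in Trem2_WT_5XFAD and 5.30% (15 of 283) in Trem2_KO_5XFAD. The microglia-like shares of the 5XFAD groups lay above these and that of creER_Syk_fl did not. Of neutrophil-like cells 21.4% (351 of 1638) did, and in each group but Trem2_WT_5XFAD their share exceeded that of microglia-like cells. Whether T cells or neutrophils express these genes was not tested, so both measures leave open how much of the shares is background. The creER difference no longer passed, at adjusted p = 0.06, without any 1 of creER_Syk_fl_5XFAD replicates 1, 2 and 3, at -8.47, -7.61 and -8.39 points. The Trem2 difference was -5.11 points without Trem2_WT_5XFAD replicate 2 and -25.1 without replicate 1.

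**Figure D4:**
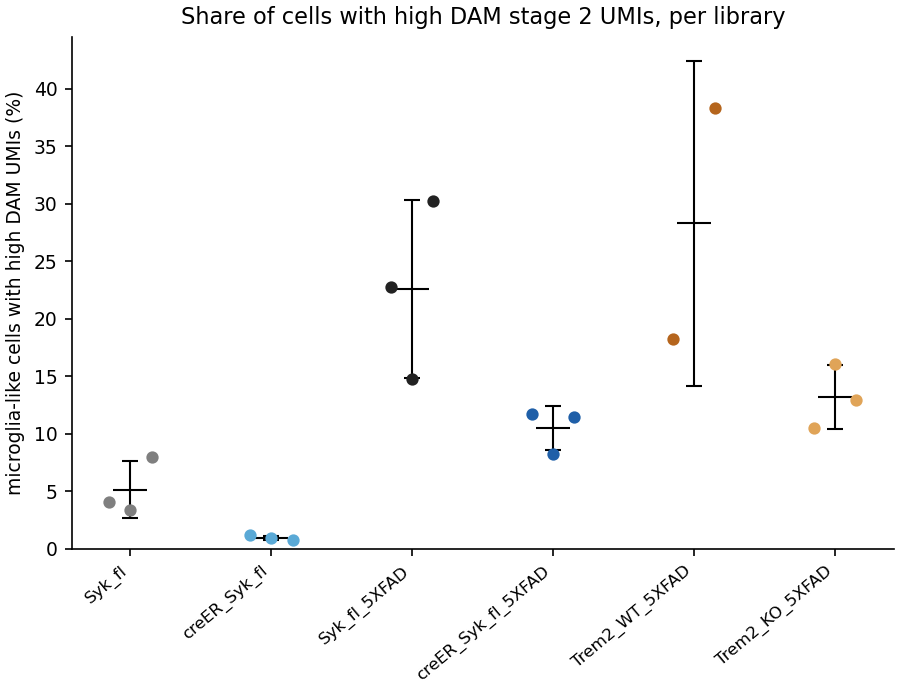
Each point is 1 library, and the vertical axis gives the percent of its microglia-like cells with high DAM stage 2 UMIs; horizontal marks and bars are the group mean and SD. All 3 Syk_fl_5XFAD libraries lie above the 3 creER_Syk_fl_5XFAD libraries, whose mean is 10.5%.

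Among all sorted cells, T cell-like cells made up 0.526% ± 0.116 in Syk_fl and 2.42% ± 1.89 in Syk_fl_5XFAD, 0.492% ± 0.0274 in creER_Syk_fl and 0.838% ± 0.488 in creER_Syk_fl_5XFAD (SD, n = 3 each). The 5XFAD difference of 1.12 points had an exact two-sided permutation p = 0.015 and an adjusted p = 0.27 over 18 tests, so no cell type passed. Border macrophage-like cells were 3.40% ± 1.37 in Trem2_KO_5XFAD (n = 3) and 1.95% ± 0.956 in Trem2_WT_5XFAD (n = 2), and neutrophil-like cells 1.97% ± 0.392 and 0.358% ± 0.133, with exact p = 0.3 and 0.1 (adjusted p = 0.74 each). Neutrophil-like cells took 6.21% ± 10.5 of creER_Syk_fl_5XFAD (n = 3) because replicate 3 held 18.4%; its microglia-like share was 68.2%.

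The cohorts themselves were compared through Trem2_WT_5XFAD and Syk_fl_5XFAD. Immediate early and dissociation genes, such as those for the Fos and Jun factors, had a mean log2 CPM of 7.60 to 8.57 in the 5 Trem2 libraries and 5.36 to 6.99 in the 12 Syk libraries. NF-kB cytokine genes likewise had at least 6.06 in the Trem2 libraries and at most 5.38 in the Syk libraries. Between these groups 4055 genes were higher and 4192 lower, so each genotype change was taken within its cohort. Only the test of the difference between the creER and Trem2 knockout changes crossed the cohorts.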

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

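Of the tests in this part, thinned cells for the lists, the arrangement of the libraries for the interaction lists, keeping the unnamed cluster, the UMIs per cell of the Trem2_WT_5XFAD libraries, the Cx3cr1 copy and the other splits of the samples were chosen only after the result was seen.

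The 5XFAD change differed between creER Syk fl/fl and Syk fl/fl, by the interaction test, for 6 genes, among them Rapsn (0.82 on the log2 scale), Gramd1b (1.08), Alpk1 (-1.39), Tmem176b (-0.70) and Hacd2 (-0.65). Gramd1b and Alpk1 lie outside the rule for named genes and were chosen after their values were seen. By camera it differed for 9 lists, with means of -1.93 for MHC class II, -1.71 for interferon response, -1.05 for DAM stage 2, -0.66 for cholesterol synthesis, -0.40 for MHC class I, -0.35 for cell cycle, -0.23 for oxidative phosphorylation, -0.20 for ribosomal protein and 1.25 for immediate early and dissociation genes. With an estimated correlation only cholesterol synthesis kept its call (adjusted p = 0.03); MHC class II stood at 0.061, interferon response at 0.178 and DAM stage 2 at 0.541, and the other 5 lists lost theirs too. Of the 100 splits of the Syk libraries drawn for the interaction, 11 gave at least the 6 genes of the real one, and the highest other split gave 1092, so chance is not excluded for this count. Splits with so many genes may point to a structure of the samples, which was not identified. The splits exchanged 5XFAD labels, so the 5XFAD change itself can enter them, and their share is not a plain chance rate. The split with 585 genes exchanged the labels within Syk fl/fl alone, which turns the interaction into the sum of both 5XFAD changes. Exchanging all labels in both genotypes only changes the sign of the interaction. Up to that sign, splits with 12, 40, 56 and 233 genes kept the Syk fl/fl groups of the real split and regrouped creER libraries alone. Others that did so gave 0. What the rest share was not tested. Other splits were also counted for 4 comparisons of 3 with 3 libraries, where 10 splits are too few for a share under 0.05. The real split, 1 of 10 each time, gave 564 genes for 5XFAD in Syk fl/fl (highest other 74), 77 for 5XFAD in creER Syk fl/fl (highest other 0), 364 for creER within 5XFAD (highest other 0) and 44 for creER without 5XFAD (highest other 0). These counts are from edgeR; the real splits had 2157, 1187, 1544 and 1396 genes at an unadjusted p under 0.05, and DESeq2 called 829, 230, 530 and 219.

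The first pattern weighed was the rise of the interferon response, MHC class II and cholesterol synthesis lists with 5XFAD in Syk fl/fl and not in creER Syk fl/fl. A difference in UMIs per cell is argued against, though only at the preset correlation. With cells thinned to equal UMIs, the highest camera adjusted p of the 3 lists in the interaction was 0.000413. Thinned cells were not tested with an estimated correlation. RNA of border macrophages, B cells and dendritic cells is argued against for MHC class II, though weakly. Their 17 tested markers had a median log2 fold change of -0.0871 with 5XFAD (quartiles -0.36 and 0.65), against 2.27 for MHC class II. Fscn1, the highest at 410 CPM, was also a leading gene of microglia-like cluster 1. Others stood near the floor, such as Cd163 at 0.128 CPM. The 1 called higher was Ms4a7 at 3.88 (0.731 CPM), while Mrc1 stood at -0.62 (5.08 CPM). For interferon response and cholesterol synthesis the markers were not a test. An arrangement of the libraries by chance cannot be told apart: the lowest adjusted exact permutation p of the 3 lists was 0.45 (20 lists; unadjusted 0.055 for interferon response, 0.085 for MHC class II and 0.09 for cholesterol synthesis), but this test was hardly able to pass. It permuted creER labels within 5XFAD status, so a change confined to 5XFAD gives nearly the same value whatever the arrangement of the libraries without 5XFAD. A loss of Syk signalling in carriers may explain the pattern and stays open, as does the Cx3cr1 copy that the creER allele replaces.

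The second pattern was that the number of genes called for Trem2 knockout, 154, rests on Trem2_WT_5XFAD replicate 2 (7 without it, 517 without replicate 1). The unnamed cluster left out of replicate 1 is argued against as the cause, since keeping it moved the mean log2 CPM of DAM stage 2 from 6.62 to 6.65, which closed 1.68% of the gap to the 8.08 of replicate 2. Fewer UMIs per cell in replicate 1 is argued against, since at an equal number of UMIs the 2 libraries still differed by 6.78 DAM stage 2 UMIs per cell, against a range of 1.42 among the knockout libraries. A difference between the mice, such as in plaque load, was not tested and may account for it.

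The third pattern was the lower NF-kB cytokine genes in creER carriers without 5XFAD. More activation during dissociation in the Syk_fl libraries is argued against as the whole cause: with the immediate early list as a covariate, the 5 called genes had a median log2 fold change of -1.14 (median SE 0.20), against -1.11 without it. With the covariate Ccl3 went from -2.73 (SE 0.40) to -2.17 (SE 0.38), Ccl4 from -3.26 (SE 0.51) to -2.71 (SE 0.50), Nfkbia from -0.78 (SE 0.15) to -0.53 (SE 0.16), Cd83 from -1.11 (SE 0.17) to -1.14 (SE 0.20) and Cxcl16 from -0.53 (SE 0.11) to -0.55 (SE 0.14). None of the 5 passed the threshold any longer by edgeR, at adjusted p from 0.0524 to 0.373, in a fit that called 6 genes in all, so part of the fall in Ccl3, Ccl4 and Nfkbia may go with dissociation. Cluster 5, with Fosb, Egr1, Jun and Fos among its leading genes, goes the same way: it made up 17.3% ± 10.8 of microglia-like cells in Syk_fl and 3.40% ± 1.83 in carriers (SD, n = 3 each), and no fit left its cells out. Loss of 1 Cx3cr1 copy cannot be told apart from Syk deletion, because 0 libraries had Cx3cr1 levels among those of the other creER label.

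Cells outside the named types exceeded the highest Syk_fl library in 3 clusters that held at least 1% of a library's sorted cells. Cluster 9 made up 3.57% of sorted cells in creER_Syk_fl replicate 2 and 4.47% in creER_Syk_fl_5XFAD replicate 3. Cluster 18, with Ttr, Jchain and Ccl3 among its leading genes, made up 16.1% in Trem2_WT_5XFAD replicate 1. Cluster 24, with the granule genes Prtn3, Elane and Mpo, made up 1.60% in creER_Syk_fl_5XFAD replicate 3. Groups of 2 or 3 libraries were not tested for a single library far from the others.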

How the results depend on the processing

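Tests chosen only after the result was seen were the fits with unnamed clusters kept and without the 2 libraries that stood apart, thinned cells for the lists, no thinning for the DAM share, and the block for the correlation and part kept. Of the values that answer a comparison, 334 stayed within their limits, 100 moved and 4 were weaker; of single genes, lists and shares, 3718 were the same, 521 weaker, 62 stronger and 19 reversed. Named genes called in every alternative were 18 of 33 for 5XFAD in Syk fl/fl, 3 of 12 for 5XFAD in creER Syk fl/fl, 18 of 32 and 2 of 9 for creER with and without 5XFAD, 0 of 4 for the interaction and 1 of 22 for Trem2 knockout. In that order the counts of called genes were 564, 77, 364, 44, 6 and 154, with 6 for creER against Trem2 knockout, from edgeR. Fits to the groups compared alone gave 311, 158, 26 for the interaction and 15 for Trem2 knockout, and to the cohort alone 26 and 15; these have fewer residual degrees of freedom. The replicate block gave 943, 215, 622, 145, 101 for the interaction and 14 for creER against Trem2 knockout. The median paired correlation of same-number libraries was 0.07 over 18 Syk pairs, of which 8 exceeded 0.1, and 0.27 over 2 Trem2 pairs, and not every library correlated best with its own number, so the numbers were not taken as pairs. Thinned cells gave 295, 205 for creER within 5XFAD and 70 for Trem2 knockout. The DESeq2 Wald test gave 230 for 5XFAD in creER Syk fl/fl, 219 for creER without 5XFAD, 123 for the interaction, 313 for Trem2 knockout and 12 for creER against Trem2 knockout, and unnamed clusters kept gave 11 for the interaction. Without the 2 libraries that stood apart the counts were 47 for 5XFAD in creER Syk fl/fl, 45 for the interaction, 494 for Trem2 knockout and 10 for creER against Trem2 knockout, the high-DAM difference by creER -8.39 points (adjusted exact p = 0.06), and the lists called 8 of 13 for 5XFAD in creER Syk fl/fl and 8 for creER against Trem2 knockout.

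Lists called were 14, 13, 13, 7, 9, 13 and 4 in the same order, and 2, 0, 2, 0, 1, 1 and 0 with an estimated correlation, where camera no longer assumes a small correlation. With fry, which asks another question, they were 5 for 5XFAD in creER Syk fl/fl, 2 for creER without 5XFAD, 2 for the interaction, 6 for Trem2 knockout and 0 for creER against Trem2 knockout. Leaving out 1 replicate gave 172 to 716 genes, 25 to 85, 150 to 420, 10 to 89, 0 to 28, 7 to 517, 5 to 11, and 7194 to 7925 between cohorts; lists ranged from 13 to 15, 9 to 13, 12 to 14, 7 to 9, 8 to 11, 6 to 14 and 3 to 10. A group left with 1 library was assumed to vary like the others. The high-DAM difference ranged from 11.6 to 15.5 points for 5XFAD, -10.1 to -6.25 for creER and -25.1 to -5.11 for Trem2 knockout. Pearson's r ranged from 0.269 to 0.556 and Spearman's rho from 0.176 to 0.372, and rho was 0.442 over genes of at least 20 CPM. The part kept ranged from 72.9% to 105% for DAM stage 1, 48.5% to 60.8% for DAM stage 2, -8.92% to 15.4% for interferon response, 0.678% to 17.3% for MHC class II, -35.6% to -23.9% for cholesterol synthesis, 36.6% to 45.3% for lysosome (25.1% over called members alone, though its medians were 0.19 in both comparisons) and 51.8% to 76.0% for ribosomal protein.

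Each reversed value was uncalled with all libraries. For creER against Trem2 knockout, glycolysis was up at adjusted p = 0.024 without the 2 libraries that stood apart and 0.0169 without Trem2_WT_5XFAD replicate 1; over single replicates its adjusted p ranged from 0.00233 (down, without Trem2_WT_5XFAD replicate 2) to 0.992. DAM stage 2 was down at 0.000118 without Trem2_WT_5XFAD replicate 2, within a range from 2.09e-05 (up, without replicate 1) to 0.961. With single replicates left out, the log2 fold change of Syk ranged from -0.0593 to 0.102 for 5XFAD in creER Syk fl/fl, from -0.0272 to 0.137 for creER without 5XFAD and from -0.228 to 0.133 for Trem2 knockout, where it was 0.132 without the 2 libraries. The interaction of Trem2 ranged from -0.15 to 0.0410 and was 0.0720 with thinned cells and 0.00276 with the stricter filter, and that of Cx3cr1 ranged from -0.0153 to 0.133. Cx3cr1 ranged from -0.0870 to 0.201 for Trem2 knockout. Apart from the smaller fits and left-out libraries, the cause was not tested. Depth limits the rarest genes, such as Gpnmb with 3 UMIs in Syk_fl.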

Other observations

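All tests and values of this part, except the test of MHC class II in border macrophage-like cells, were chosen only after the result was seen. The 4 other genes called for creER against Trem2 knockout were chosen after their values were seen: Mdfi (2.47), Treml2 (2.09), Pot1b (1.46) and Apobec2 (-1.62). In the knockout these stood at -2.04, -2.16, -1.33 and 1.89. In the annotation of the earlier build all 4 lie on the chromosome of Trem2, so a strain difference near the targeted locus was not separated from an effect of Trem2.

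Within microglia-like cells, cluster 8 (Lpl, Clec7a, Cst7, Itgax) made up 12.1% ± 3.42 in Syk_fl_5XFAD, 0.865% ± 0.0763 in creER_Syk_fl_5XFAD, 1.38% ± 0.742 in Syk_fl and 0.156% ± 0.0511 in creER_Syk_fl (SD, n = 3 each). Cluster 6 (Cst7, Fabp5, Apoe, Clec7a, Lpl), another with DAM genes, made up 5.69% ± 1.72, 6.76% ± 1.65, 4.86% ± 4.24 and 2.54% ± 0.205 in the same order, so it was not lower in carriers within 5XFAD. Cluster 7 (Ifit3, Ifit2, Isg15) made up 9.12% ± 2.96, 2.76% ± 0.478, 3.24% ± 1.33 and 3.66% ± 1.10 in the same order. In the Trem2 cohort cluster 13 (Cst7, Spp1) made up 133 of 2827 cells in Trem2_WT_5XFAD replicate 1, 708 of 4159 in replicate 2 and 1.14% ± 0.403 in the knockout (SD, n = 3), and cluster 17 (Ifit3, Isg15) 95 and 303 of the same cells against 1.41% ± 0.749. In the Syk_fl_5XFAD libraries the 5% of cells with the most interferon response UMIs held 38.3% to 43.4% of them.

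In border macrophage-like cells, Trem2 stood at a log2 fold change of -3.87 and Cst7 at -4.42 in the knockout, and Cx3cr1 at -1.25 in creER carriers without 5XFAD. Trem2 also stood at -3.47 in T cell-like cells of the knockout. Whether microglial RNA entered the border macrophage-like sums was not tested. For 5XFAD in Syk fl/fl, 5XFAD in creER Syk fl/fl and creER within 5XFAD, edgeR called 0 of 6531 genes, with 406, 319 and 274 at an unadjusted p under 0.05; DESeq2 was not used here. A lower MHC class II list in these cells, as in microglia-like cells of creER carriers within 5XFAD, was tested and not found: the list stood at a mean of 0.19 with a camera adjusted p of 0.798. This test rested on 105 cells in Syk_fl_5XFAD and 150 in creER_Syk_fl_5XFAD, with 70558 UMIs in Syk_fl_5XFAD replicate 2, so a fall could be missed. In T cell-like cells 5XFAD raised Ifi213 (2.05), Irgm1 (1.85), Rnf213 (1.75) and Isg20 (1.59) with Syk intact, and the interferon response list stood at a mean of 2.22 (adjusted p = 5.42e-14, and 0.0769 with an estimated correlation). Another 7 genes fell there, among them the microglial P2ry12 (-2.18) and Sirpa (-2.39), and creER within 5XFAD raised 52 genes such as S100a8 (6.34) and S100a9 (6.67), which neutrophils express, so RNA from other cells enters these sums.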
